A study of Rattus norvegicus with 16 samples.

How the data were processed

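The samples were 16 poly(A) RNA libraries from the lumbar spinal dorsal horn of rats, the part of the spinal cord that receives sensory input from the hind limb. They were taken 28 days after surgery. Rats were wild type (WT) or carried a knockout (KO) of LPA4, a receptor for the lipid messenger lysophosphatidic acid, and had undergone a sham operation or spared nerve injury (SNI), a surgical model of neuropathic pain. Each of the 4 groups held 4 libraries. The titles of 4 KO samples give "WT" in the place where the others name the operation. The count table's own column headers call the matching columns KO sham, and the series design names only sham and SNI operations, so these libraries were analysed as KO sham. The labels do not say whether each library came from a separate rat, so all p-values measure the spread between these libraries.

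Total RNA was purified with a Monarch miniprep kit and libraries were made with a TruSeq stranded mRNA kit, per the labels' protocols. The submitters' processing notes name fastp 0.22.0, STAR 2.7.9a and RSEM 1.3.1 and the rat build mRatBN7.2, without giving their role or order. The annotation release, the strand setting and any filter are not given in the sources used here. The authors deposited 1 table of expected counts, that is, estimated read counts per gene that need not be whole, for 30560 Ensembl rat gene IDs. Of its values, 96.4% were whole numbers within a tolerance of 1e-9, and its columns summed to different totals, so they had not been scaled to a common depth. An expected count divides reads that match several genes among them, so a gene with a near-identical copy has a less certain value.

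The table gives no gene symbols. The reference gene table used for names lists 47357 rat genes of the assembly GRCr8, and 0 of them carry an Ensembl ID there, so 0 of the 30560 IDs were matched to a symbol. The files do not pair IDs with names, and no name is given here. For that reason 3 analyses fixed before the data were examined were not run: the tests of 35 gene lists (cell types, pathways and receptor families), the count of the targeted gene in each library, and the rule for choosing named genes. In their place, the text gives 5 IDs chosen after their values were seen: the 2 with the smallest p after SNI in each genotype, both called higher, the 1 higher and the 1 lower ID called between genotypes, and the ID with the smallest p in the interaction, which edgeR did not call. IDs that were lower after SNI without being called are not named. Chromosome positions are not given because no annotation of the build was used here.

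Expected counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR 4.0.16 (minimum count 10), which left 15237 genes holding 99.97% of all counts; 10331 IDs had 0 counts in every library. Library sizes were scaled by the TMM method, and CPM values are TMM-scaled. One edgeR quasi-likelihood model with a mean per group was fitted to all 16 libraries, so that the 4 groups shared 1 estimate of the spread, in R 4.3.3. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05, and a gene past it is said to be called. The comparisons fixed before the data were examined were SNI against sham in each genotype, KO against WT after each operation, and the interaction, which tests whether the SNI effect differed between genotypes. The SNI effect averaged over genotypes and the genotype effect averaged over operations, from the same model, were added after the data were seen, as was the scoring of gene lists across genotypes. For that scoring, the 8 libraries of one genotype were fitted alone and the 100 genes with the smallest p among those higher after SNI were taken. Their mean log2 CPM, minus its mean in sham, was then compared between SNI and sham libraries of the other genotype with an exact permutation test. Log2 CPM used a prior count of 2.

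Library totals ran from 15790243 to 28090152 counts. The common biological coefficient of variation was 18.0%, and the median standard error of a log2 fold change was 0.13 in a comparison of 2 groups, 0.18 in the interaction and 0.09 in the averaged SNI effect. Where a group had 0 counts, the fold was bounded with a floor of 3 counts over the whole group. Such floors cover counting error only. The 120 pairs of libraries were compared by chi-square over 14738 genes. Each pair differed by more than sampling noise (chi-square per degree of freedom 7.65 to 118), so no library was counted as a duplicate.

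The model was tested on simulated counts made from the real means and library sizes, with known genes changed. In the simulated WT comparison it recovered 47.8% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 95.5% of those changed 4-fold. In the simulated KO comparison of SNI with sham, these shares were 53.7%, 80.6% and 90.9%. In the simulated interaction they were 28.4%, 62.7% and 84.8%. The simulation changed many genes at once, drew each gene independently and held no library that stood apart. These shares may therefore not hold for the real libraries. Alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 Wald test, voom of limma 3.58.1 with sample quality weights, the replicate number as a block, a fit over only the 8 libraries compared, and leaving out in turn each library of the groups compared. Leaving out libraries outside a comparison, which share its estimate of the spread, all alternatives for the averaged effects, and a fit without both libraries that stood apart were added after the data were seen.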

Results

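RNA from the lumbar dorsal horn was profiled in 4 WT sham, 4 WT SNI, 4 KO sham and 4 KO SNI libraries, 28 days after surgery. The design asks how gene expression in the dorsal horn changes after nerve injury, how it differs without LPA4, and whether the response to injury depends on LPA4. Library totals were 15790243 to 25096694 counts in WT sham, 18200783 to 26583679 in WT SNI, 17130951 to 24612494 in KO sham and 23890801 to 28090152 in KO SNI. Between 17033 and 17708 gene IDs had a count above 0 in a library.

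The libraries did not separate by genotype or operation on the first 2 principal components, which held 32.7% and 12.8% of the variance of log2 CPM. WT sham replicate 2, which also had the lowest total, lay at 85.5 on the first component, against -21.4 to -5.29 for the other 3 WT sham libraries. Its median correlation with the other 15 libraries was 0.949. The lowest value among those others was 0.973, in KO SNI replicate 1. Of 10500 genes with an average log2 CPM of 3 or more, 697 in WT sham replicate 2 were over 2-fold from the mean of their own group's other libraries, of which 222 were higher and 475 lower. This number was 169 in KO SNI replicate 1, 179 in WT sham replicate 4 and 21 to 97 in the remaining libraries. For the other WT sham libraries, the mean compared with included WT sham replicate 2. The median correlation of WT sham replicate 4 with the other libraries was 0.985. Both WT sham replicate 2 and KO SNI replicate 1 were kept, and counts without both are given beside the comparisons.

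The knockout was examined first. ENSRNOG00000002428 had 0 counts in all 8 KO libraries and 65 to 113 counts in each of the 8 WT libraries. It was the only ID with 0 counts in every KO library and at least 10 in every WT library, and 0 IDs showed the reverse. Its level was 4.39 ± 0.0679 CPM in WT sham and 4.26 ± 0.508 CPM in WT SNI (SD, n = 4 each). Against a floor of 3 counts over the KO group it was at least 125-fold lower in KO than in WT after sham and at least 143-fold lower after SNI (edgeR adjusted p = 4.73e-06 and 3.46e-06). The ID was chosen after its values were seen, and the files do not pair it with a name, so the count of the targeted gene itself is not reported here.

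Only 1 other gene was called between genotypes in each comparison. After sham, 2 of 15237 genes were called in KO against WT, 1 higher and 1 lower, and after SNI the count was also 2, with 1 in each direction. Both comparisons called the same pair of IDs. Without both libraries that stood apart, the counts were 1 after sham and 2 after SNI. ENSRNOG00000070277 rose from 7.27 ± 0.653 CPM in WT sham to 12.3 ± 1.64 CPM in KO sham (SD, n = 4 each), a log2 fold change of 0.76 (SE 0.11, edgeR adjusted p = 0.0266), and its KO sham and WT sham values did not overlap. After SNI it rose from 6.19 ± 0.419 CPM in WT to 11.7 ± 0.990 CPM in KO, a log2 fold change of 0.92 (SE 0.11, edgeR adjusted p = 0.00233). In the sham comparison the call of ENSRNOG00000070277 was the less secure one. It ended with the replicate number as a block (edgeR adjusted p = 0.146). Among other fits, it ended without any one of WT sham replicates 1, 2, 3 or 4, WT SNI replicate 3, KO sham replicates 2 or 3, or KO SNI replicates 3 or 4 (edgeR adjusted p up to 0.161), in the fit without both libraries that stood apart (edgeR adjusted p = 0.0863), and in that over only the 8 libraries compared (edgeR adjusted p = 0.937). At an unadjusted p under 0.05, edgeR gave 580 genes after sham and 181 after SNI, without adjustment for the number of genes tested. Both were below a share of 0.05 of the 15237 genes, which chance alone would give on average. Whether the p-values of this fit run too high was not tested. Counts below that share, here and in the comparisons that follow, therefore do not show that no other gene differed.

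**Figure D1:**
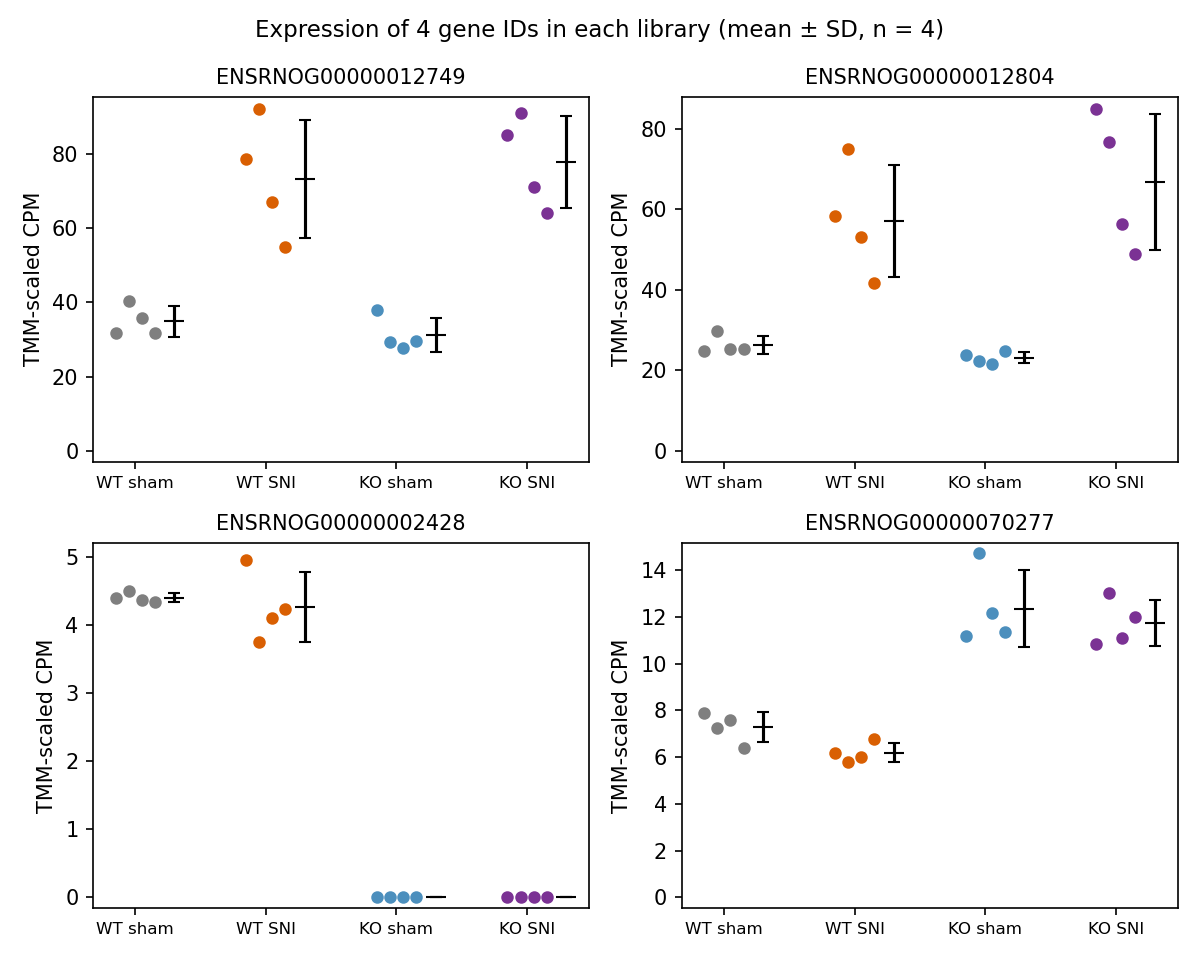
TMM-scaled CPM (vertical axes, linear) of 4 gene IDs in the 4 groups, with 1 point per library and the mean ± SD (n = 4) beside the points. ENSRNOG00000012749 and ENSRNOG00000012804 lie higher in every SNI library than in any sham library of the same genotype, ENSRNOG00000002428 is at 0 in all 8 KO libraries, and ENSRNOG00000070277 is higher in each KO group than in WT.

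SNI raised a small set of genes in WT rats. Of 15237 genes, 13 were called higher and 0 lower after SNI, with a median log2 fold change of 1.08 among the 13. ENSRNOG00000012749 rose from 34.9 ± 4.10 CPM in WT sham to 73.2 ± 15.9 CPM in WT SNI (SD, n = 4 each), a log2 fold change of 1.07 (SE 0.16, edgeR adjusted p = 0.0428). ENSRNOG00000012804 rose from 26.3 ± 2.30 to 57.1 ± 13.9 CPM, a log2 fold change of 1.12 (SE 0.18, edgeR adjusted p = 0.0428). For each of these IDs, all 4 SNI values lay above all 4 sham values. At an unadjusted p under 0.05 there were 447 higher and 271 lower genes. These 718 were fewer than a share of 0.05 of all genes tested, which chance alone would give on average. The calls lay just past the threshold, at edgeR adjusted p values from 0.0428 to 0.0468, and their number depended on single libraries. It was 0 without any one of WT sham replicates 1, 3 or 4, WT SNI replicates 1, 2 or 3, KO sham replicates 2, 3 or 4, or KO SNI replicate 2. It was 1 without KO sham replicate 1, 20 without WT SNI replicate 4 and 33 without both libraries that stood apart. DESeq2 called 65 genes (62 higher, 3 lower) and limma voom called 30 (30 higher, 0 lower). EdgeR called 45 (45 higher, 0 lower) with the replicate number as a block and 0 over the 8 WT libraries alone.

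In KO rats SNI also raised genes, and edgeR called none lower over all 16 libraries. Of 15237 genes, 16 were called higher and 0 lower, with a median log2 fold change of 1.15 and edgeR adjusted p values of 0.0025 to 0.0356. ENSRNOG00000012749 rose from 31.2 ± 4.58 CPM in KO sham to 77.8 ± 12.4 CPM in KO SNI (SD, n = 4 each), a log2 fold change of 1.32 (SE 0.16, edgeR adjusted p = 0.0025). ENSRNOG00000012804 rose from 23.2 ± 1.42 to 66.7 ± 16.9 CPM, a log2 fold change of 1.52 (SE 0.18, edgeR adjusted p = 0.0025). Both IDs kept their calls in KO under all 23 alternatives run. At an unadjusted p under 0.05 there were 552 higher and 171 lower genes. These 723 were again fewer than the share of 0.05 that chance alone would give on average. The number of calls was 3 without any one of KO sham replicates 2 or 3 or KO SNI replicates 1 or 2, 4 without KO sham replicate 4, 5 without WT sham replicate 1 or WT SNI replicate 1, and 8 without WT sham replicate 3 or WT SNI replicate 3. It was 34 without WT sham replicate 2 (all higher) or WT SNI replicate 2 (33 higher, 1 lower), 30 without KO sham replicate 1 and 10 without both libraries that stood apart. DESeq2 called 100 genes (96 higher, 4 lower) and limma voom called 22 (21 higher, 1 lower). EdgeR called 70 (70 higher, 0 lower) with the replicate number as a block and 4 over the 8 KO libraries alone.

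The genes called in the 2 genotypes overlapped. Of the 13 called in WT and the 16 called in KO, 8 were shared, where independent lists of these sizes would share 0.0137 (one-sided Fisher's exact test, p = 2.3e-22, across genes, which are not independent replicates). The number shared was 0 without any one of the 10 libraries whose removal left 0 calls in WT. It was 1 without KO sham replicate 1, 3 without KO SNI replicate 1, 49 with DESeq2 and 40 with the replicate number as a block. No library entered both comparisons, although they shared 1 estimate of the spread. All 21 genes called in at least 1 genotype were higher after SNI in both. Averaged over genotypes, SNI raised 139 genes and lowered 0 past the threshold. Their median log2 fold change was 0.76, or 1.69-fold, and 26 changed by over 2-fold. The averaged effect had 582 higher and 221 lower genes at an unadjusted p under 0.05. These 803 were above a share of 0.05 of all genes tested. All 139 were higher after SNI in each genotype taken alone, with a median of 0.69 in WT and 0.73 in KO, although the averaged test selects for this. Without WT SNI replicate 2 the count of 139 became 81, without WT sham replicate 3 it became 84 and without KO sham replicate 3 it became 88. Without both libraries that stood apart it was 156 (154 higher, 2 lower), and 124 of the 139 genes were among them. DESeq2 called 221 genes (216 higher, 5 lower), and all 139 were among them, while limma voom called 176 (175 higher, 1 lower). Fits that left out 1 library called at most 1 gene lower.

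Genes ranked in one genotype were then scored in the other, where no library had been used to choose them. Of the 100 genes ranked first for a rise after SNI in KO rats, 99 were higher after SNI in WT rats. Their mean log2 CPM was 0.77 higher in WT SNI than in WT sham (SD 0.22 and 0.20, n = 4 each), and the lowest SNI library, at 0.50, lay above the highest sham library, at 0.25, which was WT sham replicate 2. The 100 genes ranked in WT rats gave a similar picture in KO rats: 98 were higher, and their mean was 0.75 higher in KO SNI than in KO sham (SD 0.24 and 0.15, n = 4 each). An exact permutation test gave p = 0.0286 for each list, two-sided, the smallest value that 70 arrangements allow.

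**Figure D2:**
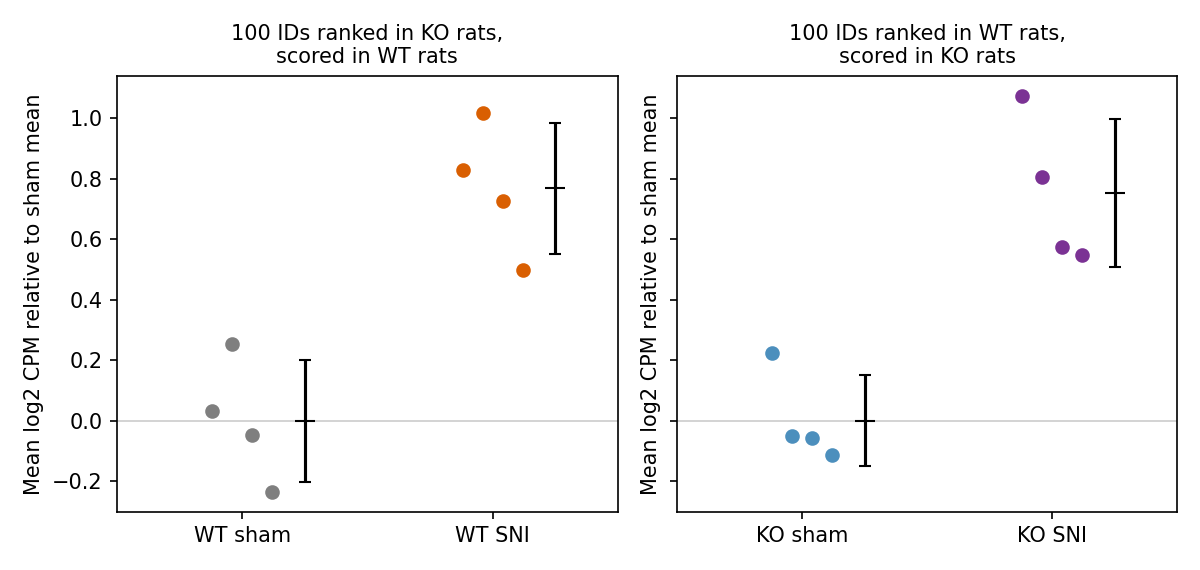
Mean log2 CPM relative to the sham mean (vertical axis) of the 100 genes ranked first for a rise after SNI in KO rats, in the 8 WT libraries (left), and of the 100 ranked in WT rats, in the 8 KO libraries (right), with the mean ± SD (n = 4) beside the points. All 4 SNI libraries lie above all 4 sham libraries in both panels, by 0.77 on average on the left and 0.75 on the right.

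By edgeR, no gene's response to SNI was shown to differ between genotypes. The interaction called 0 of 15237 genes by edgeR (smallest adjusted p = 0.981), with 455 genes at an unadjusted p under 0.05. That was below a share of 0.05, which chance alone would give on average. DESeq2 called 1 gene and limma voom called 0, and edgeR without both libraries that stood apart called 0. For ENSRNOG00000012749 the SNI effect was 0.25 larger in KO on the log2 scale (95% confidence interval -0.21 to 0.71), and for ENSRNOG00000012804 it was 0.40 larger (-0.12 to 0.92), so both intervals include 0. Among the 139 genes, 3 had an interaction p under 0.05, also below a share of 0.05. The smallest adjusted p over these genes alone was 0.990 by edgeR. The mean response of the 139 genes on the log2 scale was 0.84 ± 0.22 in KO SNI and 0.78 ± 0.21 in WT SNI (SD, n = 4 each). The difference, KO minus WT, was 0.06 (95% confidence interval -0.36 to 0.48), and -0.01 (-0.44 to 0.42) without WT sham replicate 2. Differences between genotypes of up to 0.48 in this mean response therefore remained within the interval over all libraries. An exact permutation test of KO SNI against WT SNI libraries gave p = 0.714, two-sided. It took the sham means as fixed, so it left out the spread of the sham libraries.

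The ID with the smallest interaction p was ENSRNOG00000017086, the 1 gene that DESeq2 called. It had 13.7 ± 1.60 CPM in WT sham, 21.9 ± 6.63 in WT SNI, 22.0 ± 6.13 in KO sham and 11.5 ± 0.578 in KO SNI (SD, n = 4 each). Its interaction was -1.61 on the log2 scale (SE 0.32, edgeR adjusted p = 0.981), against -1.62 with DESeq2 (adjusted p = 0.0118). Within WT SNI and within KO sham, 1 library each lay at 12.4 and 12.8 CPM, apart from the other 3 of its group.

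Over all 15237 genes, the SNI effects in WT and KO were not correlated (Pearson r = -0.0214, Spearman rho = -0.0169, across genes, which are not independent replicates), and 47.9% of genes had the same sign. The value was -0.255 over genes with an average log2 CPM of 3 or more and -0.118 without the 139 genes called in the averaged effect. It also depended on single libraries, most of all on WT sham replicate 2. Without WT sham replicate 2, r was 0.449 (Spearman rho 0.270) and 58.8% of genes had the same sign. Without that library and the 139 genes, r was 0.395 (Spearman rho 0.251). Without both libraries that stood apart r was 0.215. Leaving out any other library gave r from -0.184, without WT SNI replicate 3, to 0.163, without KO SNI replicate 1.

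**Figure D3:**
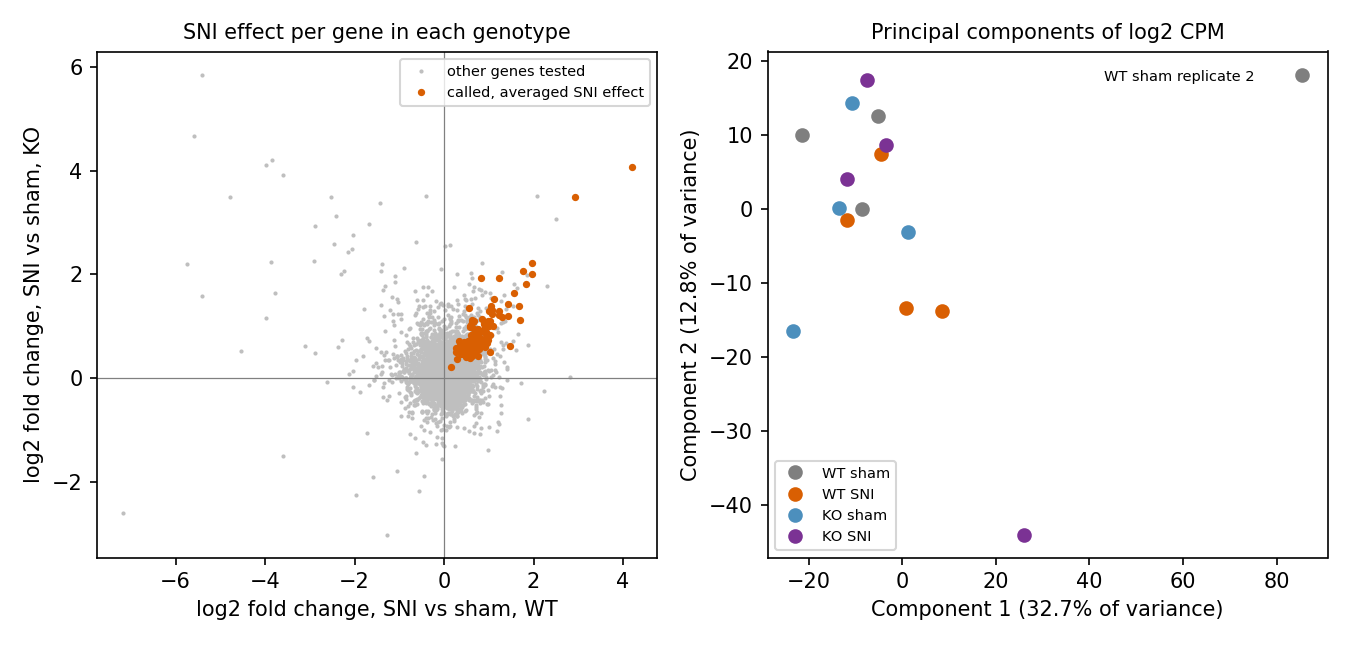
Left, the log2 fold change after SNI in WT (horizontal axis) and in KO (vertical axis) for each of 15237 genes, with the 139 genes called in the averaged SNI effect in orange, all higher in both genotypes. Right, the 16 libraries on the first 2 principal components of log2 CPM, which hold 32.7% and 12.8% of the variance, coloured by group, with WT sham replicate 2 at 85.5 on the first.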

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

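The test by thinning was chosen before its result was seen; the tests of the label, of genes shared with other libraries, of dilution and of separate levels were chosen after the results had been seen. Of 34 sets of 4 libraries checked for 1 value far from the rest, 5 held such a value, where chance gives about 1 in 20.

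WT sham replicate 2 had a median correlation of 0.949 with the other libraries, against 0.985 to 0.987 in the other WT sham libraries, and lay at 85.5 on the first principal component. Depth did not account for this: with all libraries thinned to the total of this library, its median correlation was 0.951 (mean of 10 draws), still below the lowest of the others, 0.973. A library of another of the 4 groups under this label was considered. A KO library was argued against by the 65 counts of 1 ID in WT sham replicate 2. That ID had 0 counts in all KO libraries and at least 10 in each of the other 7 WT libraries. A WT SNI library was argued against less firmly. The score of WT sham replicate 2 over the 100 genes ranked in KO rats was 0.25, below the lowest WT SNI library, 0.50. That score was also above those of the other WT sham libraries, -0.24 to 0.03. RNA of other cells may contribute the genes that were higher: of 58 IDs over 8-fold above the median of the other libraries, 40 were also over 2-fold higher in KO SNI replicate 1 and 30 in WT SNI replicate 3, although the source is not identified without gene names. Dilution by such RNA would lower all genes of the tissue alike, yet after scaling 337 IDs were over 4-fold lower than the median of the other libraries, against at most 92 in any other, so the lower genes stay unexplained, an outside sample or a different dissection stays open, and no biological explanation was tested.

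KO SNI replicate 1 had a median correlation of 0.973 with the other libraries, against 0.987 in the other 3 KO SNI libraries. ENSRNOG00000012804 was at 29.7 CPM in WT sham replicate 2, against 24.7 to 25.4 CPM in the other WT sham libraries.

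ENSRNOG00000017086 was at 12.8 CPM in KO sham replicate 2, against 24.0 to 25.9 CPM in the other KO sham libraries, and its interaction was -1.62 on the log2 scale with DESeq2 (adjusted p = 0.0118, from 0.0118 to 1.0 over the alternatives run), so the SNI effect differed in that tool. Over all 16 libraries its values left a gap, with 10.8 to 15.5 CPM in 10 libraries and 22.6 to 26.9 CPM in 6, with none between. Of 10500 IDs, 17 including this one had a gap over 0.4 of their range with at least 4 libraries on each side, where normal values give 5.41, and 5 of them, not including this one, had a gap over 0.5 of it, where normal values give 0.368, so chance gaps were argued against for the set but stay open for this ID. Of the 17, 13 including this one had a gap over 0.5 on the log2 scale. At most 1 of the 13 parted the libraries in any one way. A single difference that parts all of these IDs alike, such as a batch or sex, was therefore argued against. Only identical partings were counted, so a difference that acts on some of the IDs, or with exceptions, stays open. Inherited variants that differ between rats are a candidate explanation that was not tested, and they could give an apparent interaction by the way they fall among groups of 4.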

How the results depend on the processing

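The averaged effects, the overlap of calls, the difference in mean response, leaving out libraries outside a comparison and the fit without both libraries that stood apart were chosen after the data were seen. The tests of the 35 gene lists, with their alternatives, were not run. DESeq2 size factors and no low-count filter moved no count of calls by over 1.5 times. DESeq2 called 65 genes for SNI in WT, 100 in KO, 49 in both, 221 for the averaged effect and 1 for the interaction. Limma voom called 30 in WT and 13 in both. Fits over only the 8 libraries compared called 0 in WT, 4 in KO and 1 for KO against WT after sham, with fewer samples to estimate the spread. Without both libraries that stood apart, the counts were 33 in WT, 10 in KO and 1 for KO against WT after sham, and the correlation of SNI effects was 0.215. It was -0.255 over genes with log2 CPM of 3 or more. The causes of these changes were not tested, also for the smaller fits.

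Over all genes tested, the replicate numbers gave no clear pairing of the libraries. Of 24 pairs with the same number, 6 correlated above 0.1 (range -0.357 to 0.226), and 1 library correlated best with its own number. Over the 139 genes raised by SNI, replicate 4 had the lowest mean log2 CPM relative to the sham mean in each group. It was -0.21 in WT sham, 0.52 in WT SNI, -0.12 in KO sham and 0.67 in KO SNI, and replicate 3 was next lowest. This order was seen after the fact, so a pairing that acts on these genes stays open. With the replicate block, the counts were 45 in WT, 70 in KO, 40 in both and 1 for KO against WT after sham, where ENSRNOG00000070277 was no longer called (edgeR adjusted p = 0.146); the block moved no other count by over 1.5 times.

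Leaving out 1 library at a time gave 0 to 20 calls for SNI in WT, 3 to 34 in KO, 0 to 10 in both, 81 to 177 for the averaged effect, 1 to 2 for KO against WT after sham, 2 to 3 after SNI and 0 for the interaction. The correlation ran from -0.184 to 0.449. The difference in mean response, KO minus WT, ran from -0.0361 to 0.140; it changed sign to -0.0106 without WT sham replicate 2, -0.0245 without WT SNI replicate 4 and -0.0361 without KO SNI replicate 1, and passed no threshold. ENSRNOG00000002428 in both comparisons, ENSRNOG00000070277 after SNI and both SNI IDs in KO kept their calls in all 23 alternatives, while ENSRNOG00000012749 kept its call in WT in 12 and ENSRNOG00000012804 in 11. At the depth, spread and number of libraries here, simulated 1.5-fold changes were recovered in 47.8% of cases for SNI in WT. The simulation drew genes independently and held no library that stood apart, and the part of depth in this was not tested.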

Other observations

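The test of shared variation and the counts of other splits of the libraries were chosen before their results were seen; the averaged effects and the check without KO SNI replicate 1 were chosen after.

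The genes raised by SNI varied together within groups. Over the 139 genes, the mean pairwise correlation of the deviations from the group means was 0.461 across 16 libraries, where the highest of 1000 random lists matched on expression gave 0.0339. It was 0.398 without WT sham replicate 2 and KO SNI replicate 1, 0.564 over the 8 SNI libraries and 0.322 over 7 sham libraries. As a hypothesis, 1 shared source that varies between libraries may set the level of most of these genes. It could be the number or state of 1 kind of cell or the exact piece of tissue taken. In each group, replicates 3 and 4 had the lowest mean levels of these genes, an order seen after the fact. A source shared by libraries of the same replicate number therefore stays open too. Random lists hold no pathways, so sets of co-regulated genes in general would also exceed them, and without gene names the kind of cell was not tested.

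Other ways of parting the libraries into groups of the same sizes gave fewer calls in most comparisons. For SNI in WT, 1 of 35 splits, the real one, gave as many as 13 genes, and the highest other gave 1. For SNI in KO, 1 of 35 gave as many as 16, and the highest other gave 0. For the averaged SNI effect, 1 of 100 gave as many as 139, and the highest other gave 1. Under 0.05 of the splits gave as many as each of these 3 real counts, without adjustment for the number of comparisons split. This argues against chance for each count as a whole, but not for any single gene called. For KO against WT, 1 of 35 splits gave 2 genes after sham (highest other 1) and 1 of 35 gave 2 after SNI (highest other 0). Averaged over operations, where 2 genes were called, 2 of 100 splits gave as many (highest other 2). Of the 2 genes called between genotypes, 1 was ENSRNOG00000002428, with 0 counts in every KO library, a difference that splits mixing the genotypes break up. The splits therefore cannot tell whether chance gave the call of the other, ENSRNOG00000070277, and no conclusion is drawn for it. For the interaction the real count was 0, so all 100 splits gave at least as many by construction (highest other 2), and the splits say nothing about it.

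Of the 13 IDs with a gap over 0.4 of their range and over 0.5 on the log2 scale, some of which chance gaps alone would give, 12 had libraries on both sides of the gap within at least 3 of the 4 groups, and 7 within all 4. The exception was ENSRNOG00000017086, with libraries on both sides in WT SNI and KO sham only. Their gaps ran from 0.54 to 4.48 on the log2 scale, with a median of 1.82. None of the 13 was among the 139 genes raised by SNI, and none followed the groups of the design.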
